A study of Mus musculus with 8 samples.

How the data were processed

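The samples were 8 libraries from 4 C3H10T1/2 lines, with 1 HA ChIP library and 1 library of the input DNA (5% of the lysate, per the labels' protocols) for each of H3.1WT, H3.1K36M, H3.3WT and H3.3K36M. Groups were taken from the genotype and description fields of the labels. The titles of both H3.3 ChIP samples begin with an H3.1 name, and the genotype field, which says H3.3, was followed. The labels' protocol text names a Cbx2 antibody while the sample descriptions name an HA antibody, and the description was followed.

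Per the submitters' processing notes, Bowtie 1.0.0 and the mouse build mm9 were used. How reads were counted in bins, whether duplicates were removed or reads extended, and which peak caller, threshold and control were used is not given in the sources used here. The authors deposited a table of RPM per genomic bin for the 4 HA libraries and lists of peak positions for H3.1K36M and H3.3K36M. Input libraries and peaks of the WT lines were not used here. In each RPM column, 100% of the values were whole multiples of the smallest value above 0, within 0.01 of a read, so the reads per bin were recovered. Those steps were 0.0283 RPM (H3.1WT), 0.0241 (H3.1K36M), 0.0215 (H3.3WT) and 0.0259 (H3.3K36M). The columns summed to between 0.429% and 0.512% above the nominal RPM total. The recovered totals count reads as the table holds them. All peak positions lay on a 200 bp grid with no score or fold value per peak, and whether peaks were called on 1 library or on more is not given in the sources used here. Coordinates are printed 1-based in mm9.

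Of the table's 253926 rows, 251622 lay on chromosomes 1 to 19 and X. Of these, 247593 were 10 kb wide and 4029 were wider. Rows of 20 kb held about 2.01 to 2.03 times the RPM of their neighbours, so wider rows are sums and were left out of the main analysis. Bins of 10 kb with a mean of at least 0.5 RPM over the 4 libraries were kept, 245206 bins or 2452.1 Mb. Ratios are log2 of RPM plus a pseudocount of 0.1 RPM, which understates the change of low bins. A bin was counted as different at 2-fold, a rule of size and not a test, since each group has 1 library. Folds of named regions are ratios of RPM with exact (Clopper-Pearson) 95% intervals on the recovered reads. These intervals cover counting error only, and reads without molecular identifiers are not independent molecules. Regions named for an extreme ratio were ranked on the same reads. Their folds therefore tend to be overstated, and the intervals do not allow for this choice.

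Named regions were chosen by a rule fixed before the data were examined: the 10 merged neighbouring regions with the highest and the 10 with the lowest ratio of each comparison, where the mean of the compared libraries was at or above the median, and the 10 longest peaks of each list. How neighbours merge was set later, as touching bins at least 2-fold apart in the same direction. Of the regions named in the text, the H3.1K36M peak cluster on chromosome 1 and the rows with the highest signal were chosen after their values were seen. The gene table at hand describes another build, GRCm38.p6, so no gene was placed on the bins, and the 19 gene lists fixed in advance and the histone gene part of the rule were not analysed here. Whether a named region lies in a gene, exon or intron is therefore not given.

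Overlap of peaks was at least 1 base, counted with bedtools 2.31.1, and was compared with 10000 random placements of the H3.1K36M peaks on their own chromosomes. Signal inside peaks was also set beside 10000 draws of bins matched in 50 classes of mean signal, which are not reported because the peaks were called in a library of the ratio. For the classes of H3.3 enrichment, recovered WT reads were divided at random, with one portion ranking the bins by H3.3WT over H3.1WT and the other giving the ratios of K36M over WT; classes from H3.3K36M over H3.1K36M, with the K36M reads divided, were added after seeing the data. The ratio and interval steps were tested on simulated data, in which reads were drawn for all 245206 bins with counting error alone and 200 bins were changed. In the simulation of H3.3K36M against H3.3WT, bins changed 4-fold had a median log2 ratio of 1.97 and 100% of them passed the 2-fold rule. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.

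Alternatives fixed before the data were examined were pseudocounts of 0.01 and 1 RPM, no filter and a filter at the median signal, scaling by the median of bin ratios, autosomes only, Spearman's rho, 100 kb bins, the top and bottom 1% of bins left out of the correlations, other overlap rules, placement only in bins with signal, the longer part of each peak list, and summed signal per chromosome. Added after seeing the data were the wider rows, the median of all bins or of each chromosome subtracted, the top and bottom 1% of bins left out of the comparisons, the overlap without the chromosome 1 cluster, the alternatives for the percentile ratio of each library, and an exact binomial test on the recovered reads with Benjamini-Hochberg adjustment at 0.05, which compares the sequenced libraries and not the conditions.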

Results

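Chromatin carrying epitope-tagged histone H3 was profiled by HA chromatin immunoprecipitation and sequencing (ChIP-seq) in C3H10T1/2 cells, a line of mesenchymal progenitors from C3H mouse embryos. The 4 cell lines each stably expressed 1 FLAG-HA-tagged histone, which was H3.1 or H3.3, as wild type (WT) or with the K36M change, a lysine-to-methionine replacement in the histone tail. H3.1 is the variant deposited mainly during DNA replication, and H3.3 is also deposited outside replication, at active genes and regulatory elements among other places. Each line gave 1 HA library and 1 input library, and the 4 HA libraries are analysed here as RPM (reads scaled to the library total) in 10 kb bins of the mouse genome build mm9. The HA libraries held 35487141 reads (H3.1WT), 41705735 (H3.1K36M), 46749609 (H3.3WT) and 38783917 (H3.3K36M), recovered from the RPM steps. This depth gave medians of 129, 151, 129 and 116 reads per bin over the 245206 bins used. With 1 library per line, no difference between lines has a replicate check, and every interval below covers counting error only. The intervals of regions ranked by their ratio do not allow for that ranking, which favours extreme values.

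The HA signal of H3.1 was spread almost evenly over the genome, whereas that of H3.3 formed regions of high and low signal. Input libraries were not used here, so background reads and the efficiency of the immunoprecipitation cannot be told apart from the placement of the histones. The signal at the 90th percentile of bins was 2.18 times that at the 10th percentile in H3.1WT and 2.09 times in H3.1K36M, against 5.83 times in H3.3WT and 4.13 times in H3.3K36M. In H3.3WT, 23.1% of bins lay at least 2-fold above the library's median of 2.77 RPM, and in H3.3K36M 15.4% lay at least 2-fold above a median of 3.004 RPM. The same share was 1.84% in H3.1WT and 1.60% in H3.1K36M. Bins at the 10th percentile held 1.35 RPM in H3.3WT and 1.76 RPM in H3.3K36M, while bins at the 90th percentile held 7.89 and 7.28 RPM, so H3.3K36M spanned less between these percentiles. At the 99th percentile H3.3K36M was the higher, with 14.01 RPM against 13.48 RPM.

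**Figure D1:**
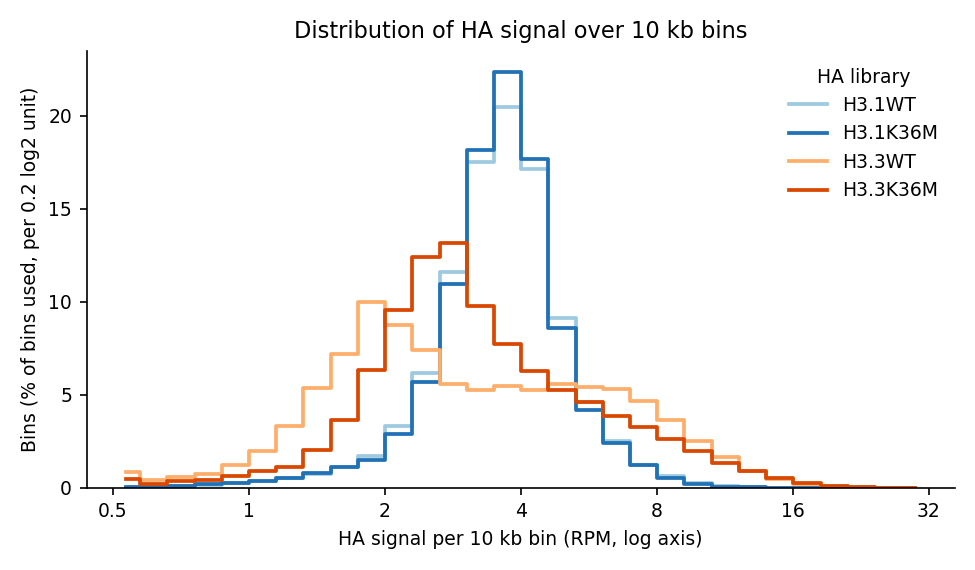
Share of 10 kb bins (% of the bins used, per 0.2 log2 unit) by HA signal in RPM on a log axis, with 1 line per HA library; bins below 0.5 RPM are counted in the lowest class and bins above 32 RPM are not drawn. The H3.1 libraries form a single peak around medians of 3.65 RPM (H3.1WT) and 3.64 RPM (H3.1K36M), and the H3.3 libraries spread to both sides.

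Profiles of the same variant resembled each other more than profiles that shared the WT or K36M state. Across bins, which are not independent replicates, Pearson's r of log2 RPM was 0.884 between H3.1WT and H3.1K36M (Spearman's rho 0.819) and 0.861 between H3.3WT and H3.3K36M (rho 0.828). The 4 pairs of an H3.1 with an H3.3 library had r between 0.494 and 0.526. With only the bins at or above the median signal, r fell to between 0.00955 and 0.0255 for these 4 pairs. It fell to 0.833 for the H3.1 libraries and 0.752 for the H3.3 libraries. This filter picks bins by the mean of the same 4 libraries, which by itself can lower r, so the fall does not show unrelated profiles.

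The comparison of H3.3K36M with H3.3WT asks whether the mutation changes where H3.3 sits. Long stretches carried several times more HA signal in H3.3K36M: at chr14:95480001-95550000 it was 12.2 RPM per 10 kb against 1.85 RPM in H3.3WT, a 6.61-fold difference (95% interval 6.06 to 7.22). The signal in H3.3K36M was also 5.86-fold higher (5.53 to 6.21) over 110 kb at chr10:102960001-103070000 and 5.36-fold higher (4.97 to 5.79) over 80 kb at chr8:53150001-53230000. It was 5.80-fold higher (5.18 to 6.51) at chr14:95570001-95610000, just past the first chromosome 14 region. No 10 kb bin was used between these chromosome 14 regions. Bins past them stayed higher in H3.3K36M up to chr14:95690001-95700000, with 9.84 against 2.58 RPM, so both may be parts of a longer stretch. The region with the highest ratio was a single bin, chr7:131810001-131820000, at 7.90-fold (5.76 to 11.1). In the other direction, chr11:22480001-22490000 was 3.96-fold lower in H3.3K36M (2.89 to 5.53), with 1.24 RPM against 4.92 RPM. Also lower in H3.3K36M were chr8:25590001-25600000, by 3.72-fold (3.05 to 4.56), the 70 kb region chr9:116970001-117040000, by 3.62-fold (3.28 to 4.00), and chr15:61080001-61110000, by 3.46-fold (3.04 to 3.95). At chr9:116970001-117040000 the H3.3K36M signal of 1.82 RPM lay below H3.1WT at 2.39 RPM and H3.1K36M at 3.45 RPM, and H3.3WT stood above all of them at 6.60 RPM.

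**Figure D2:**
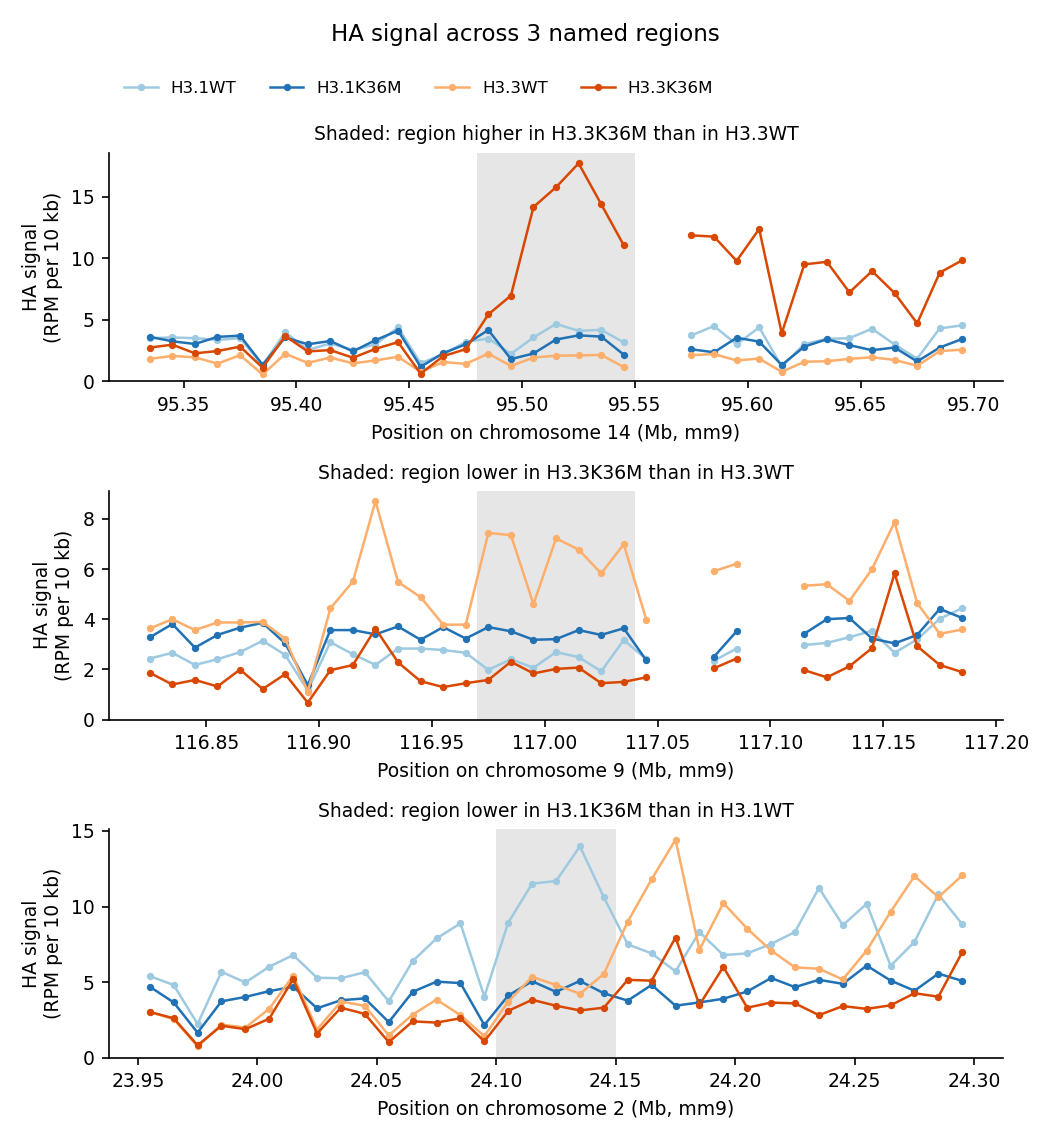
HA signal in RPM per 10 kb bin against position in Mb (mm9), with 1 line per HA library, across 3 named regions that are shaded; lines break where a 10 kb row is missing. H3.3K36M stands apart at chr14:95480001-95550000 with 12.2 RPM, H3.3WT at chr9:116970001-117040000 with 6.60 RPM, and H3.1WT at chr2:24100001-24150000 with 11.3 RPM.

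Over the genome, 7211 bins were at least 2-fold higher in H3.3K36M and 4434 at least 2-fold lower, where a simulation with counting error alone gave 14 and 22. Scaling by the median of bin ratios moved the median log2 ratio from 0.10 to -0.02, a shift of -0.12, and turned the split to 4586 bins higher and 7280 lower, so that the higher share of these bins was 61.9% as deposited and 38.6% after that scaling. The filter at the median signal also turned the order, with 2302 higher and 3361 lower, and a pseudocount of 1 RPM gave 1808 and 1663. Bins that were higher in H3.3K36M went from a median of 1.55 RPM in H3.3WT to 3.73 RPM, and bins that were lower went from 6.21 RPM to 2.62 RPM. The lower bins were the more clustered: 28.3% lay in runs of at least 50 kb, the longest of 300 kb, against 8.15% and 230 kb for the higher bins. Differences extended over long distances, with r of 0.752 between the log2 ratios of adjoining bins and 0.597 at 100 kb.

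The ratio of H3.3K36M over H3.3WT was lower in bins rich in H3.3 in the WT lines, but most of this trend depended on the library that formed the classes. Bins were divided into 10 equal classes by the ratio of H3.3WT to H3.1WT, with separate random portions of the WT reads for the classes and for the K36M ratio. In the H3.3-poorest class the median log2 ratio of H3.3K36M over H3.3WT was 0.46 (SD 0.13 over the 20 chromosomes), which is 0.36 above the median of all bins. It was -0.26 (SD 0.12) in class 8 and -0.14 (SD 0.15) in the H3.3-richest class, or -0.36 and -0.24 relative to all bins. H3.3WT enters the classes and the ratio, so a deviation of that library alone gives a fall. With classes from H3.3K36M over H3.1K36M, which push the other way, the medians were 0.17 (SD 0.11) in the poorest class, -0.08 (SD 0.13) in class 9 and 0.06 (SD 0.14) in the richest. In H3.1 the classes by WT lines had medians between -0.02 and 0.03. H3.3K36M peaks were found in 0.106% of bins in the poorest class and in 23.2% of bins in the richest.

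**Figure D3:**
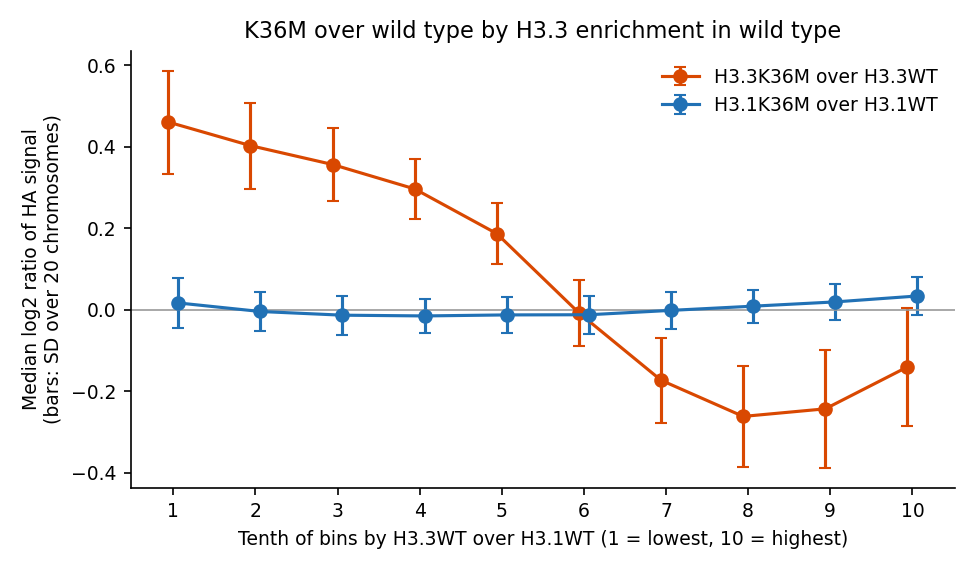
Median log2 ratio of K36M over WT HA signal (y axis) in 10 classes of bins ordered by H3.3WT over H3.1WT (x axis), for H3.3 and H3.1; error bars are the SD of the class median over 20 chromosomes. The H3.3 line falls from 0.46 in class 1 to -0.26 in class 8 and ends at -0.14, and the H3.1 line stays between -0.02 and 0.03; H3.3WT enters both axes of the H3.3 line.

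H3.1K36M and H3.1WT were close over nearly the whole genome. The SD of the log2 ratio over bins was 0.24, against 0.18 from counting error alone, and 30 bins were at least 2-fold higher in H3.1K36M and 157 at least 2-fold lower. The lower bins had a high signal in H3.1WT, with a median of 6.96 RPM against 3.25 RPM in H3.1K36M. They included chr15:43580001-43590000, which was 2.66-fold lower (2.19 to 3.22), chr4:88580001-88590000, 2.62-fold lower (2.07 to 3.33), and the 50 kb region chr2:24100001-24150000, 2.48-fold lower (2.29 to 2.68). Of the 10 regions with the lowest ratio, 3 lay close together on chromosome 16, at chr16:86150001-86160000, chr16:86230001-86240000 and chr16:86310001-86320000, with 8.86, 10.9 and 12.1 RPM in H3.1WT and 3.76, 4.48 and 4.84 RPM in H3.1K36M. Near the end of chromosome X, chrX:166070001-166080000 and chrX:166090001-166100000 were 2.35-fold (1.97 to 2.82) and 2.51-fold (2.08 to 3.03) lower. On the higher side the ratios were smaller, and 5 of the 10 regions lay on chromosome 9, led by chr9:107230001-107240000 at 2.07-fold (1.65 to 2.62). The median of the whole of chromosome 9 lay 0.11 above that of all bins in this ratio, which by itself lifts its bins in the ranking. The count of higher bins depended on the pseudocount and filter: it was 0 with a pseudocount of 1 RPM, 51 with 0.01 RPM and 95 with no filter. The count of lower bins was 39, 186 and 192 with these settings.

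Over all bins the ratio of K36M over WT in H3.3 had little relation to that in H3.1, with r of 0.0468 across bins (rho 0.0321) and values from -0.0426 to 0.195 within single chromosomes. In 100 kb bins r was 0.154. These ratios share no library. In 76.4% of the 157 bins lower in H3.1K36M, H3.3K36M was lower than H3.3WT, against 41.6% of all bins. Their medians were 7.89 RPM in H3.3WT and 5.10 RPM in H3.3K36M. The median of all bins in H3.3WT was 2.77 RPM, so all bins are not a baseline matched on H3.3 signal. Of the 30 bins higher in H3.1K36M, 60% were higher in H3.3K36M, against 58.4% of all bins. Of the 10 regions lowest in H3.1K36M, 9 were lower in H3.3K36M as well. Of the 10 highest in H3.1K36M, 8 were also lower in H3.3K36M and 2 were higher. At chr15:43580001-43590000 both mutant libraries were low, with 10.0 RPM in H3.1WT, 3.78 RPM in H3.1K36M, 11.1 RPM in H3.3WT and 3.6001 RPM in H3.3K36M. The exception among the lowest was chr4:88580001-88590000, with 6.57 and 2.51 RPM in H3.1WT and H3.1K36M and 14.3 and 16.2 RPM in H3.3WT and H3.3K36M.

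In WT lines, H3.3 exceeded H3.1 most at chr15:31110001-31120000, by 10.2-fold (7.67 to 13.8), at chr13:21870001-21880000, by 10.2-fold (7.25 to 14.9), and at chr11:33040001-33060000, by 9.49-fold (7.86 to 11.6). H3.3K36M peaks overlapped 8 of the 10 regions with the highest ratio. Lowest was chr13:68250001-68260000, with 1.25 RPM in H3.3WT and 6.20 RPM in H3.1WT, 4.97-fold lower (3.71 to 6.76), and 4 of the 10 lowest regions were on chromosome 18. The median of the whole of chromosome 18 was -0.21 relative to all bins in this ratio, which by itself lowers its bins in the ranking. Over all bins 25286 were at least 2-fold higher in H3.3WT and 41171 at least 2-fold lower, or 48164 and 4277 after scaling by the median of bin ratios, which raised the median log2 ratio by 0.41. The higher share of these bins was thus 38.0% as deposited and 91.8% after scaling. The bins 2-fold lower in H3.3WT had medians of 1.53 RPM in H3.3WT and 3.62 RPM in H3.1WT, against 3.65 RPM over all bins in H3.1WT. The filter at the median signal gave 24207 higher and 5368 lower. That filter takes the mean of the 4 libraries, so low H3.3 signal itself takes bins out. A pseudocount of 1 RPM gave 17700 and 4546. The bins 2-fold higher in H3.3WT as deposited had medians of 3.11 RPM in H3.1WT and 8.51 RPM in H3.3WT, and 23.3% of them held an H3.3K36M peak.

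In K36M lines, the regions with the highest ratio of H3.3 over H3.1 were chr11:73130001-73140000 at 11.99-fold (8.99 to 16.3), chr11:50190001-50200000 at 10.4-fold (8.05 to 13.7), chr13:63190001-63200000 at 9.94-fold (8.17 to 12.2) and chr7:144490001-144500000 at 10.0-fold (7.55 to 13.5), in the order of their log2 ratios with the pseudocount. The 80 kb region chr3:45020001-45100000 was 9.23-fold higher (8.36 to 10.2), with 12.1 RPM in H3.3K36M against 1.31 RPM in H3.1K36M and 3.14 RPM in H3.3WT. H3.1WT held 2.95 RPM there, so the low H3.1K36M signal adds to this ratio, and no H3.3K36M peak overlapped the region. The bin chr6:72380001-72390000 was among the 10 highest in both states, at 7.997-fold in WT and 9.07-fold in K36M. At chr13:77570001-77580000 the order was the opposite, with 82.0 RPM in H3.1K36M and 15.9 RPM in H3.3K36M. H3.1WT at 56.4 RPM and H3.3WT at 18.9 RPM were high there too. Near the starts of their chromosomes, chr3:3000001-3010000 and chr17:3010001-3040000 were also among the 10 lowest. There were 20070 bins at least 2-fold higher in H3.3K36M and 8057 at least 2-fold lower, or 30473 and 1027 after scaling by the median of bin ratios, which raised the median log2 ratio by 0.28 and the higher share of these bins from 71.4% to 96.7%. The bins 2-fold lower in H3.3K36M had medians of 1.66 RPM in H3.3K36M and 3.76 RPM in H3.1K36M, against 3.64 RPM over all bins in H3.1K36M. The filter at the median signal, which low H3.3 signal itself affects, gave 19532 higher and 1242 lower. A pseudocount of 1 RPM gave 15024 and 388. Across bins, the ratio of H3.3 over H3.1 in WT lines and that in K36M lines had r of 0.769 (rho 0.675).

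Whole chromosomes differed between the H3.3 lines. Relative to the median of all bins, the median log2 ratio of H3.3K36M over H3.3WT was 0.26 on chromosome 18, 0.19 on chromosome 13 and 0.14 on chromosome 6, and it was -0.30 on chromosome 15. Chromosome 18 held 754 bins at least 2-fold higher and 17 at least 2-fold lower in H3.3K36M, and chromosome 15 held 53 and 568. In H3.1 the chromosome medians lay closer together, from -0.08 on chromosome 18 to 0.11 on chromosome 9. Of H3.3WT over H3.1WT, the highest medians relative to all bins were 0.42 on chromosome 11 and 0.39 on chromosome 15, and the lowest was -0.23 on chromosome X. Of H3.3K36M over H3.1K36M, chromosome 19 was highest at 0.13 and chromosome 9 lowest at -0.20.

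**Figure D4:**
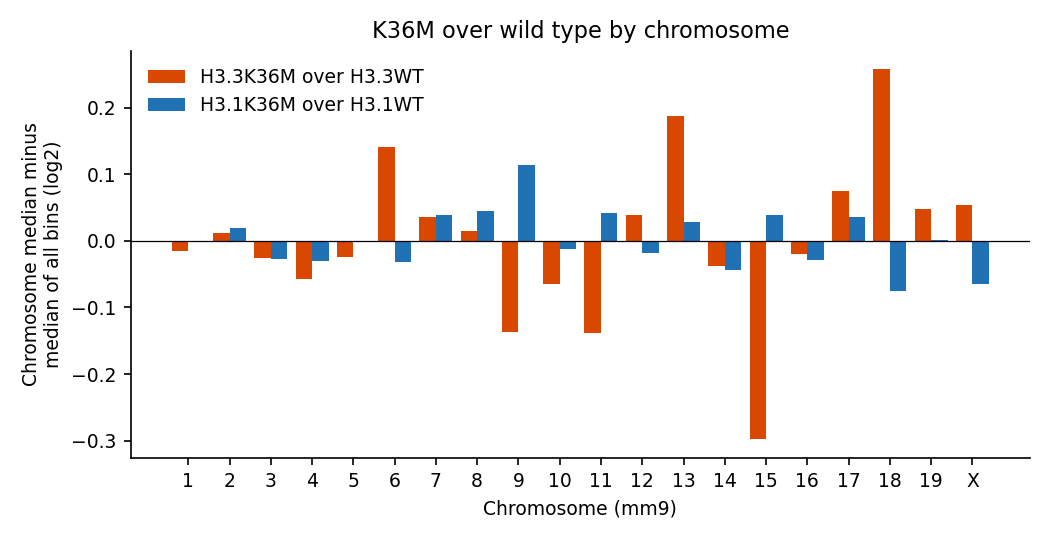
Bars give the median log2 ratio of K36M over WT on each chromosome minus the median of all bins, for H3.3 and H3.1. In H3.3, chromosome 18 stands highest at 0.26 and chromosome 15 lowest at -0.30; the H3.1 bars lie between -0.08 and 0.11.

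The authors' deposited peak lists, given as positions with no score, held 8375 H3.3K36M peaks covering 31.7 Mb and 73 H3.1K36M peaks covering 0.204 Mb. Median lengths were 2 kb and 1.6 kb. The longest H3.3K36M peaks were chr4:88652201-88754200 (102 kb), chr11:117784001-117883600 (99.6 kb), chr13:63329801-63428200 (98.4 kb) and chr11:118152001-118242200 (90.2 kb). Bins in the first of these averaged 17.7 RPM in H3.3K36M, 14.3 RPM in H3.3WT, 8.36 RPM in H3.1WT and 6.93 RPM in H3.1K36M. H3.3K36M peaks were densest on chromosome 19, with 5.53 per Mb, and on chromosome 15, with 4.88 per Mb, and sparsest on chromosome X, with 0.942 per Mb. The longest H3.1K36M peak was chr8:87324601-87347800 (23.2 kb), and 11 of the 73 lay within 109.6 kb at chr1:33879001-33988600.

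H3.1K36M peaks overlapped H3.3K36M peaks more often than random placement on the same chromosomes gave, but the placements were not matched on HA signal. At least 1 base was shared by 15 of the 73 (20.5%), against a mean of 2.01 and a highest value of 9 in 10000 random placements. They belonged to 10 of the 52 clusters formed by H3.1K36M peaks less than 50 kb apart, and without the cluster on chromosome 1 the overlap was 11 of 62. Within 10 kb of an H3.3K36M peak lay 35 of the 73, against a mean of 6.90 by chance. Peaks in both lists included chr1:33942401-33955000, where bins averaged 15.5 RPM in H3.1WT, 15.1 RPM in H3.1K36M, 18.6 RPM in H3.3WT and 17.0 RPM in H3.3K36M, and chr4:62169201-62177800, where H3.3WT averaged 26.95 RPM and H3.3K36M 21.5 RPM.

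Bins with an H3.3K36M peak were rich in H3.3 in both H3.3 lines. In these 10413 bins the median signal was 8.86 RPM in H3.3WT and 9.43 RPM in H3.3K36M, which is 3.19-fold and 3.14-fold above the libraries' medians, whereas H3.1WT and H3.1K36M were at 3.88 and 3.76 RPM. The median log2 ratio of H3.3K36M over H3.3WT was 0.13 (SD 0.14 over chromosomes). These bins were selected by peaks called in H3.3K36M, which by itself can raise the ratio, so the value is no sign of a difference between the lines. Of the peak bins, 401 (3.85%) were at least 2-fold higher in H3.3K36M than in H3.3WT and 21 at least 2-fold lower, against 2.94% and 1.81% of all bins. Bins with an H3.1K36M peak, 83 in number, were high in every HA library, at 10.1 RPM in H3.1WT, 10.7 RPM in H3.1K36M, 9.55 RPM in H3.3WT and 10.0 RPM in H3.3K36M. Their median log2 ratio of H3.1K36M over H3.1WT was 0.07 (SD 0.11 over chromosomes), again in bins selected by the mutant library.

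**Figure D5:**
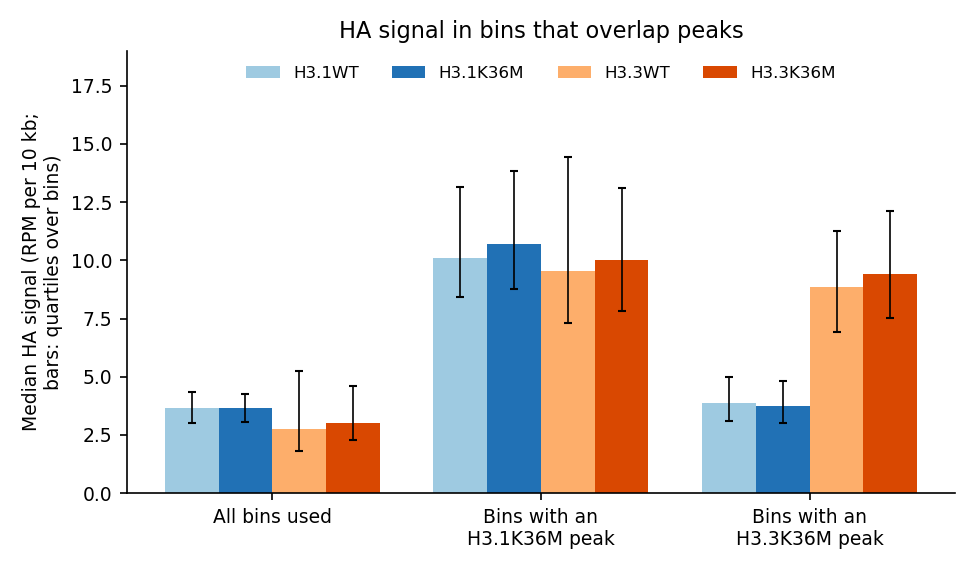
Bars give the median HA signal in RPM per 10 kb over all bins used, bins with an H3.1K36M peak and bins with an H3.3K36M peak, by HA library; error bars run from the lower to the upper quartile over bins. H3.1K36M peak bins are high in all 4 libraries (9.55 to 10.7 RPM), and H3.3K36M peak bins are high in the H3.3 libraries (8.86 and 9.43 RPM).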

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

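Among the tests below, those of an even background over the whole genome, of a deviation of H3.3WT alone, of enrichment specific to the mutant, of extra copies in the H3.3 libraries, of raised signal in every library and of copy number in 1 named line were chosen after the result was seen. So were the number of chromosomes with as wide a range and the minimum shift of 0.05 for a chromosome to be listed.

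Chromosomes 9, 18 and X moved in opposite directions in H3.1 and H3.3, by at least 0.05 from the median of all bins in each; the difference was not tested, since each group has 1 library. The shift of K36M over WT in H3.3 minus that in H3.1 was -0.25 on chromosome 9 (-0.14 in H3.3 and 0.11 in H3.1), 0.33 on chromosome 18 (0.26 and -0.08) and 0.12 on chromosome X (0.05 and -0.07). On chromosome X the H3.3 shift became -0.03, the sign of H3.1, once the median of each class of H3.3 enrichment was subtracted. Chromosome Y, which no comparison used, held 29.3 RPM in H3.1WT, 28.5 in H3.1K36M, 17.4 in H3.3WT and 19.1 in H3.3K36M. These sums hold 1035, 1184, 808 and 736 reads over 212 bins, above the 3 reads that a count of 0 allows for the sum, though the median bin held only 0.0849, 0.0964, 0.043 and 0.0518 RPM.

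H3.3K36M spanned less than H3.3WT between the 10th and 90th percentiles of bins. Regression to the mean from counting noise was excluded: with classes and ratios from separate reads, the H3.3-poorest class still lay 0.60 (SD 0.09 over chromosomes) above the richest in log2 ratio, on all 20 chromosomes. An even background in the H3.3K36M library, as the whole cause, would make the ratio fall steadily with enrichment, but the richest class lay 0.12 (SD 0.06) above class 8, on all 20 chromosomes. For the bins at least 2-fold apart such a background cannot be told apart from other causes: 4461 bins lay at least 2-fold from the best mixture against 8 in a simulation, and the lower bins had a median of 2.62 RPM where the mixed libraries had 6.21 and 3.53 RPM, but the bins were picked for their ratio, the limit set in advance (1.5 times the simulated count) took counting error as the only noise and assumed the background's profile, and the spread between libraries of 1 line is not known. A deviation of the H3.3WT library alone stays open for the trend: with classes from H3.3K36M over H3.1K36M the poorest class lay 0.11 (SD 0.09) above the richest, on 18 of the 20 chromosomes, and the efficiency of the immunoprecipitation, the amount of tagged histone and the K36M change itself may contribute, untested.

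H3.1K36M peaks lay in bins that were high in H3.1WT too. Enrichment specific to the mutant would need a median log2 ratio of at least 0.5 in those bins, and the value was 0.0679 (SE 0.03), although a narrower difference within a 10 kb bin is not excluded. Extra copies of regions reaching 100 kb from the peaks would raise the bins at 50 to 100 kb as much. With all peaks pooled, the excess there was 30.0% (SE 2.79) of that in the peak bins in H3.1K36M and 26.8% (SE 3.11) in H3.1WT. This argues against such copies as the whole cause for the H3.1 peaks as a set. Copies of shorter regions, or at single peaks, are not excluded. In H3.3K36M the excess was 69.3% (SE 5.89) and in H3.3WT 80% (SE 8.33), which leaves extra copies open for H3.3. Sequence or chromatin that gives more reads in any library could be at work, but the value for it, 2.77-fold (SE 0.23) over the median in the lowest library, H3.1WT, restates the pattern and decides nothing. Shorter repeats and shared biology of tagged H3 stay open as well, and input libraries were not used here.

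Chromosome 18 was shifted up and chromosome 15 down in H3.3K36M over H3.3WT, and the number of H3.3-poor or H3.3-rich bins did not account for this: with the median of each enrichment class subtracted, the shift was still 0.20 on chromosome 18 (SD of the other chromosomes 0.09) and -0.20 on chromosome 15 (SD 0.08). A different copy number in the H3.3K36M line would give an even shift and cannot be told apart from an uneven one: on chromosome 18 the shift was 0.25 in the H3.3-poorest class, -0.03 in class 5 and 0.38 in the richest, a range of 0.41 (SE 0.05) that 1 of the other 19 chromosomes (X, 0.42) reached, and on chromosome 15 the range was 0.16 (SE 0.03), which 3 of the other 19 reached. The 13 other autosomes shifted by less than 0.1, a set chosen after the values were seen, had at most 0.11. On chromosome 18 the range lay far above this for its SE, which goes against an even shift there but does not exclude it. On chromosome 15 it lay closer, at 0.16 (SE 0.03), which decides nothing. In the H3.3WT line a different copy number would also move bins between classes, and it is a candidate explanation: with the shift removed from H3.3WT the range was 0.11 (SE 0.03) on chromosome 18 and 0.125 (SE 0.03) on chromosome 15, against at most 0.126 on those 13 autosomes, in each case by less than the SE. Any other change of H3.3WT signal along a whole chromosome would give the same, and line and genotype are confounded, because each line gave 1 HA library.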

How the results depend on the processing

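The subtraction of medians, the binomial test, the wider rows, the bins left out of comparisons, the overlap without the chromosome 1 cluster and the alternatives for the percentile ratios were chosen after seeing the data. No paired analysis was possible because each group has 1 library. HA over input and the gene lists were not run, and values as deposited are the main values. A count was taken as kept within 1.5 times, and another value within its SD over chromosomes. By this measure 127 of 194 values kept theirs, 66 moved and 1 reversed. The reversed value, for H3.3K36M over H3.1K36M on chromosome 19, set summed signal against a median with another baseline, as described below. A count could only be kept or moved, so a turned order of higher and lower bins was never tallied as reversed. Scaling by the median of bin ratios turned that order for H3.3K36M against H3.3WT and for H3.3WT against H3.1WT. Of 240 values for named regions 161 stayed within their counting interval and 79 left it. None changed sign, but the alternatives run on these regions could not change it. A pseudocount keeps the sign, and scaling moved the median log2 ratios by at most 0.41, below the smallest named ratio of 0.88. Counting error alone gave an SD of 0.18 for K36M over WT in H3.1 and in H3.3. The SD observed was 0.24 in H3.1 and 0.49 in H3.3, so counting error was the larger part in H3.1. The cause was not tested except where a filter or scaling acts by its construction.

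Counts are given as bins higher and lower. With a pseudocount of 1 RPM, H3.3K36M against H3.3WT gave 1808 and 1663, H3.1K36M against H3.1WT 0 and 39, H3.3WT against H3.1WT 4546 lower, and H3.3K36M against H3.1K36M 388 lower; with 0.01 RPM, H3.1K36M had 51 higher. With no filter H3.1K36M had 95 higher, and with the filter at the median signal 7 higher. The latter filter gave H3.3K36M over H3.3WT 2302 higher and 3361 lower, the reverse of the order as deposited. It gave H3.3WT over H3.1WT 5368 lower and H3.3K36M over H3.1K36M 1242 lower. Fewer bins were counted with it, and low signal in a compared library itself lowers the mean it uses. Scaling by the median of bin ratios gave 4586 and 7280 (H3.3K36M against H3.3WT), 48164 and 4277 (H3.3WT against H3.1WT) and 30473 and 1027 (H3.3K36M against H3.1K36M). Subtracting the median of all bins gave 4748 and 6695, 49221 and 3365, and 31461 and 804. Subtracting each chromosome's median gave 4317 higher and 6173 lower for the H3.3 pair, 47153 and 4542 for the WT lines, and 31200 and 623 for the K36M lines. The exact binomial test, on 100% whole reads, called 53345 and 43437 (H3.3), 1963 and 3580 (H3.1), 65306 and 127659 (WT lines) and 103064 lower with 50587 higher (K36M lines); it compares libraries, without a minimum size.

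For H3.1WT with H3.1K36M, r was 0.921 with no filter, 0.833 with the median filter, 0.911 in 100 kb bins, 0.857 without the extreme 1% and 0.819 as Spearman's rho. For H3.3WT with H3.3K36M it was 0.752 with the median filter and 0.828 as rho. Between variants, no filter gave 0.594 (H3.1WT with H3.3WT), 0.631 (H3.1WT with H3.3K36M), 0.585 (H3.1K36M with H3.3WT) and 0.630 (H3.1K36M with H3.3K36M), and the median filter gave 0.0218, 0.0255, 0.00955 and 0.0244. In 100 kb bins H3.3K36M had 0.6096 with H3.1WT and 0.619 with H3.1K36M, and without the extreme 1% 0.450 and 0.449. The ratio of H3.3 over H3.1 in WT and K36M lines had r of 0.807 in 100 kb bins and rho of 0.675, and the K36M effect of H3.3 and H3.1 had 0.154 in 100 kb bins.

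With the median filter the 90th over the 10th percentile was 3.69 in H3.3WT and 3.27 in H3.3K36M. H3.1K36M peaks within 10 kb of the other list were 35. In bins at least 50% covered by H3.3K36M peaks, H3.1K36M over H3.1WT was -0.0785. From summed signal, H3.3WT over H3.1WT was 0.35 on chromosome 11 (median -0.02) and -0.38 on chromosome X. H3.3K36M over H3.1K36M was -0.30 on chromosome 9 and 0.20 on chromosome 19, where the median was -0.17. These measures have different baselines: the median of all bins was -0.43 for the WT lines and -0.30 for the K36M lines. Signal summed from libraries scaled to their totals holds no such offset. Chromosome 19 lay 0.13 above the median of all bins, so its change of sign is no change of direction.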

Other observations

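The bins below with the highest signal were picked after their values were seen, and no test was run on them.

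A single bin took more than 1% of the reads of each library, and more in H3.1 than in H3.3. This bin, chr2:98500001-98510000, held 3.68% of the reads of H3.1WT, 4.06% of H3.1K36M, 1.75% of H3.3WT and 1.63% of H3.3K36M, a ratio of H3.1 over H3.3 of 2.10 in WT and 2.49 in K36M lines. At much lower shares, the same order was seen at chr6:103590001-103600000, with ratios of 2.36 and 2.34, at chr9:35110001-35120000, with 2.15 and 2.83, and at the start of the chromosome 9 sequence, where chr9:3000001-3010000 had 2.27 and 2.84. K36M over WT was near 1 at these places, from 0.902 to 1.08 in H3.3 and from 1.07 to 1.19 in H3.1. All 4 libraries were very high there, with 630 RPM in H3.3K36M at chr9:3000001-3010000 as the lowest value. Input libraries were not used here, so these ratios cannot be read as histone placement.

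Chromosome 4 held several of the contrasts around its longest H3.3K36M peak. The peak chr4:88652201-88754200 and the shorter chr4:88543801-88608400 were high in both H3.3 lines, and in the shorter one bins averaged 6.37 RPM in H3.1WT against 3.85 RPM in H3.1K36M. Bin chr4:88580001-88590000, inside it, was among the 10 regions lowest in H3.1K36M.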
